A study of Mus musculus with 9 samples.

How the data were processed

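Total RNA of epidermal sheets from 9 mice was hybridised to Affymetrix mouse expression arrays, 1 array per mouse, after labelling with a kit that primes at the 3' end of transcripts, per the labels' protocols. The epidermis had been scratched off frozen skin. The labels assign 5 arrays to mice with floxed Alox12b and the tamoxifen-dependent Cre, called inactivated here, and 4 to floxed littermates without Cre, called controls, and they number the mice as biological replicates.

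The authors deposited 1 table of log2 values, 1 column per array, for 45037 probe sets. The tool affy, an R package for reading and summarising Affymetrix arrays, is named without a version in the submitters' processing notes. The background correction, normalisation and summary method are not given in the sources used here, nor is the base of the logarithm. The highest value of each array, 13.47 to 13.53, lies above 11.1, the natural logarithm of the largest scanner value, and the values were read as log2. No Affymetrix control probe sets were among the rows used here, so the planned check of RNA quality from the difference between 3' and 5' control probe sets was not run. All 9 columns were used, as deposited, with no filter on dim probe sets. Summarised array values are compressed near background and near the top of the range, so folds of very dim or very bright transcripts are understated.

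Probe sets were named from the platform annotation. It gave 34945 probe sets 1 gene symbol and 932 several, and 9160 were not listed and stay unnamed. No symbol needed updating against the RefSeq gene table of assembly GRCm38.p6. No gene was named from a probe set with several symbols. Each of 18193 genes was represented by its probe set with the highest mean over all 9 arrays. For 9010 genes with more than 1 probe set this was a choice, and 194 genes had probe sets that passed the threshold in both directions.

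Groups were compared per probe set with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, without covariates. Residual degrees of freedom were 7, and p-values were adjusted by the method of Benjamini and Hochberg over all 45037 probe sets, with a threshold of adjusted p 0.05. At least 2-fold means an absolute log2 difference of 1 or more. Single values were compared by an exact permutation test over all 126 splits of the arrays into 5 and 4. Before the data were examined, 44 gene lists were written, of which 15 hold cell type markers; 825 of their 932 genes were measured. They were tested with camera (preset correlation between genes of 0.01, lists of at least 3 measured genes, adjusted over the 44 lists). They were also tested with camera with an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction. Adjustment over a list alone used the same p-values for the list's measured members.

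The named genes were fixed by a rule before the data were examined. It takes the lipoxygenase list, the 12 genes with the largest rise and the 12 with the largest fall among genes that passed without overlap of the groups, up to 4 members of each list with the lowest adjusted p (up to 2 where none passed), and up to 2 members that passed against the direction of a list's test. It gave 209 genes. Predicted genes and some members were left out of the text for brevity, and genes named outside the rule are said to be so.

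The steps were tested on simulated arrays with the spread of the real ones, with 200 of 45037 probe sets changed in each of 5 runs. The inactivated-against-control fit recovered 45.6% of changes of 0.5 on the log2 scale, 89.6% of 1, 99.6% of 2 and 100% of 4. Of its calls, 5.96% were false. Far more probe sets, 12900, passed in the real comparison than were changed here. The adjusted threshold depends on that share, so these recovery rates do not carry over to the real comparison. On 18193 simulated genes, in 20 runs, camera called 100% of lists of 20 genes shifted by 1 and 10% of unshifted lists. The runs are too few to tell the latter from the nominal 1 in 20. Simulated genes varied independently, so this rate does not cover lists whose genes vary together. The sex of each mouse, which the labels do not give, was read from Xist and Y-linked probe sets. It was used as a covariate, for within-sex values, for group effects that differ by sex and for the place of inactivated replicate 5.

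Alternatives were quantile normalisation, cyclic loess and subtraction of array medians; a filter on dim probe sets at the median or 25th percentile; an intensity trend with a robust prior; no moderation; array weights; the replicate number as a block; the mean of all probe sets of a gene; removal of probe sets that can match several transcripts; a threshold of 0.01; and leaving out each array in turn. Sex was also tried as a covariate. For the gene lists, sex as a covariate and quantile normalisation were added after the data were seen.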

Results

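The series compared epidermis from adult hairless mice (SKH1 background, 5 backcross generations) in which Alox12b had been inactivated with epidermis from littermates that kept the gene. Alox12b encodes the R-specific epidermal lipoxygenase, an enzyme that oxidises the linoleate carried by skin barrier ceramides. Mice of both groups carried floxed Alox12b alleles and received 3 tamoxifen injections of 1 mg at 8 weeks of age, and only the inactivated group also carried a tamoxifen-dependent Cre recombinase driven by the keratin 14 promoter. Epidermis was taken 6 days after the treatment and hybridised to Affymetrix whole-genome mouse arrays, 5 for the inactivated group and 4 for the controls, which the labels call biological replicates. Values are on a log2 scale, with array medians of 4.34 to 4.42 and highest values of 13.47 to 13.53. The number of arrays limits the precision, and for arrays no read depth applies.

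The comparison asked which transcripts differed in epidermis 6 days after Alox12b was inactivated. In the epidermis of the inactivated group, all 13 measured stress-type cornified envelope transcripts (Sprr and Lce3 genes) rose, with a median of 4.20, as did 15 of 24 antimicrobial proteins and alarmins, 5 of 8 stress keratins and 19 of 24 kallikreins and other desquamation proteases. With an estimated correlation these lists were not called, with adjusted p of 0.294, 0.380, 0.454 and 0.294. The inactivated group had far lower levels of the suprabasal keratins Krt2 and Krt77. Fibroblast markers fell in 15 of 17 members, with a median of -1.12 (camera adjusted p = 0.487 with an estimated correlation). Of 18193 genes, 2816 were higher and 3434 lower (34.4%; limma with Benjamini-Hochberg adjustment), and of these 442 were higher and 608 lower by at least 2-fold. At least 8-fold differences were found in 49 higher and 25 lower genes. Over all 45037 probe sets, 5698 were higher and 7202 lower. The groups did not overlap in 5757 genes (31.6%), against 1.59% expected by chance.

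The first principal component held 63.4% of the variance and separated the groups. Controls scored from -63.0 to -48.6 on it, inactivated replicates 1 to 4 from 44.9 to 55.8, and inactivated replicate 5 scored 25.3. Without inactivated replicate 5, 2847 genes were higher and 3585 lower. Array medians were 4.363 ± 0.0163 (SD, n = 5) in the inactivated group. They were 4.407 ± 0.0211 (SD, n = 4) in the controls (two-sided exact permutation p = 0.0238). The interquartile range of the array values was 3.82 ± 0.0683 (SD, n = 5) in the inactivated group and 3.98 ± 0.0257 (SD, n = 4) in the controls (two-sided exact permutation p = 0.0159). The labels give no sex. Levels of Xist and Y-linked transcripts split the arrays into 3 female and 2 male mice in the inactivated group and 1 female and 3 male mice among the controls. Of the 12900 probe sets that passed, 100% kept their sign among the males and 99.8% among the females. They had been chosen on these same arrays, and the females include 1 control, so such agreement was nearly fixed in advance. With sex in the model 2617 genes were higher and 3373 lower. The controls carried no Cre, so loss of Alox12b and the presence of active Cre went together in every array.

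Differences below are inactivated minus control on the log2 scale ± SE from limma, over 5 and 4 arrays. For each gene said to have risen or fallen, every array of one group lay beyond every array of the other, except for Cxcl2, Ctla4, Kit, Vwf, Emcn, Cidea, Scd3, Sox10 and Hba-a1. The calls of these genes, and of Alox12, Capn1, Dhcr7, Hk1, Fcgr1, Tnni2, Mb and Bpgm, were lost when some single arrays were left out. A further probe set of Cd247, Etv4, Rrm1, Sgms2 and Synpo2 had the opposite sign and did not pass. Gene lists were compared with all other genes by camera, a test with a preset correlation between genes, and 16 of 44 lists passed. None of these calls held with an estimated correlation, for which the adjusted p is given beside each.

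Alox12b itself, read by a single probe set (1418266_at), was 9.89 ± 0.29 (SD, n = 5) in the inactivated group and 9.28 ± 0.10 (SD, n = 4) in the controls. It rose by 0.61 ± 0.14 (adjusted p = 0.00694; two-sided exact permutation p = 0.0159, where the smallest that 126 splits can give is 0.00794). The sources used here do not give the position of this probe set relative to the floxed part of the gene. The value therefore checks nothing about the deletion, and the group names rest on the labels.

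Of the other lipoxygenases, Alox8 and Alox12e changed by more than 2-fold. Alox8, which oxygenates arachidonic and linoleic acid, rose 15.7-fold (3.97 ± 0.27, adjusted p = 6.52e-06), while the epidermal lipoxygenase Alox12e fell by 5.38 ± 0.41 (adjusted p = 1.27e-05). Sdr9c7, the dehydrogenase that acts on the oxidised acylceramide, rose by 1.15 ± 0.09 and the epoxide hydrolase Ephx3 by 0.88 ± 0.09. Alox5, Alox5ap and Alox12 fell by 0.60, 0.48 and 0.30. Aloxe3, which takes the product of Alox12b, differed by -0.19 ± 0.09 (adjusted p = 0.143), and Alox15, Ephx1 and Ephx2 did not pass, with 0.52, 0.17 and -0.48. The list of 12 lipoxygenases and hepoxilin pathway genes thus had 4 higher, 4 lower and 4 not passing (5 and 4 adjusted over the list alone), and camera did not call it (adjusted p = 0.780).

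Among 23 enzymes and receptors of the prostaglandin and leukotriene pathways, 8 rose, 4 fell and 11 did not pass (8 and 5 adjusted over the list alone; camera adjusted p = 0.181). The phospholipases Pla2g4d and Pla2g4e, which release fatty acids from membranes, rose by 5.21 ± 0.15 (37.1-fold) and 2.94 ± 0.13. Akr1b8, an aldo-keto reductase, rose by 2.01 ± 0.19. The leukotriene receptor Cysltr1 fell by 1.20 ± 0.11 and the prostaglandin receptor Ptger4 by 1.90 ± 0.19.

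Enzymes and transporters of acylceramide synthesis rose more often than they fell, with 16 of 28 members higher, 6 lower and 6 not passing (16 and 7 adjusted over the list alone). Camera called the list higher (adjusted p = 0.00636), but not with an estimated correlation (adjusted p = 0.294 with an estimated correlation). The ceramide synthase Cers3 rose by 1.41 ± 0.10, the serine palmitoyltransferase subunit Sptlc2 by 1.32 ± 0.10, the dihydroceramide hydroxylase Degs2 by 2.27 ± 0.18 and the glucosylceramide synthase Ugcg by 1.50 ± 0.12. The sphingomyelin synthase Sgms2 fell by 1.68 ± 0.23 and the enoyl reductase Tecr by 0.72 ± 0.10.

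All 13 measured stress-type envelope genes rose, with a median of 4.20 (13 adjusted over the list alone). Camera gave an adjusted p of 4.06e-14 for this list, and an adjusted p = 0.294 with an estimated correlation. Sprr2i rose by 6.18 ± 0.29 (72.3-fold), Lce3a by 5.61 ± 0.35 (48.7-fold), Sprr2f by 5.36 ± 0.30 and Sprr2d by 4.26 ± 0.14. The pseudogene Sprr2j-ps and Lce3b rose by 5.38 ± 0.33 and 4.42 ± 0.25, and transcripts of such near-identical families can share probes. These small proline-rich and late cornified envelope proteins are crosslinked into the envelope of the outermost keratinocytes. Members of the constitutive envelope and filaggrin family behaved differently from one another, with 8 of 34 higher, 6 lower and 20 not passing (9 and 6 adjusted over the list alone; camera adjusted p = 0.247). Repetin (Rptn) rose by 3.28 ± 0.20, cornifelin (Cnfn) by 1.65 ± 0.10 and the transglutaminases Tgm3 and Tgm5 by 2.15 ± 0.21 and 1.15 ± 0.11. Lce1m fell by 2.35 ± 0.29 and sciellin (Scel) by 0.77 ± 0.11. Loricrin (Lor), filaggrin (Flg) and involucrin (Ivl), singled out after their values were seen, did not pass, with -0.19, 0.11 and 0.26.

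Of the 8 stress keratins, which appear in wounded or hyperproliferative epidermis, 5 rose and 3 did not pass (6 adjusted over the list alone; camera adjusted p = 0.000325, adjusted p = 0.454 with an estimated correlation). Krt16 rose by 3.43 ± 0.17 (10.8-fold), Krt6a by 2.65 ± 0.22, Krt6b by 2.31 ± 0.18 and Krt17 by 0.66 ± 0.07. In the inactivated group Krt6b lay at 13.51 ± 0.02 (SD, n = 5), at the top of the array range, where further increases can no longer be read. Among 13 basal and suprabasal keratins, 2 rose, 5 fell and 6 did not pass (4 and 5 adjusted over the list alone; camera adjusted p = 0.181). Krt77 fell by 7.09 ± 0.67 (136-fold lower), from 12.85 ± 0.11 (SD, n = 4) to 5.76 ± 1.63 (SD, n = 5), and Krt2, a keratin of the upper epidermis, fell by 7.05 ± 0.44 (133-fold lower). The basal keratin Krt15 fell by 3.22 ± 0.21, while Krt14 rose by 0.47 ± 0.06 and Krt78 by 0.52 ± 0.13.

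**Figure D1:**
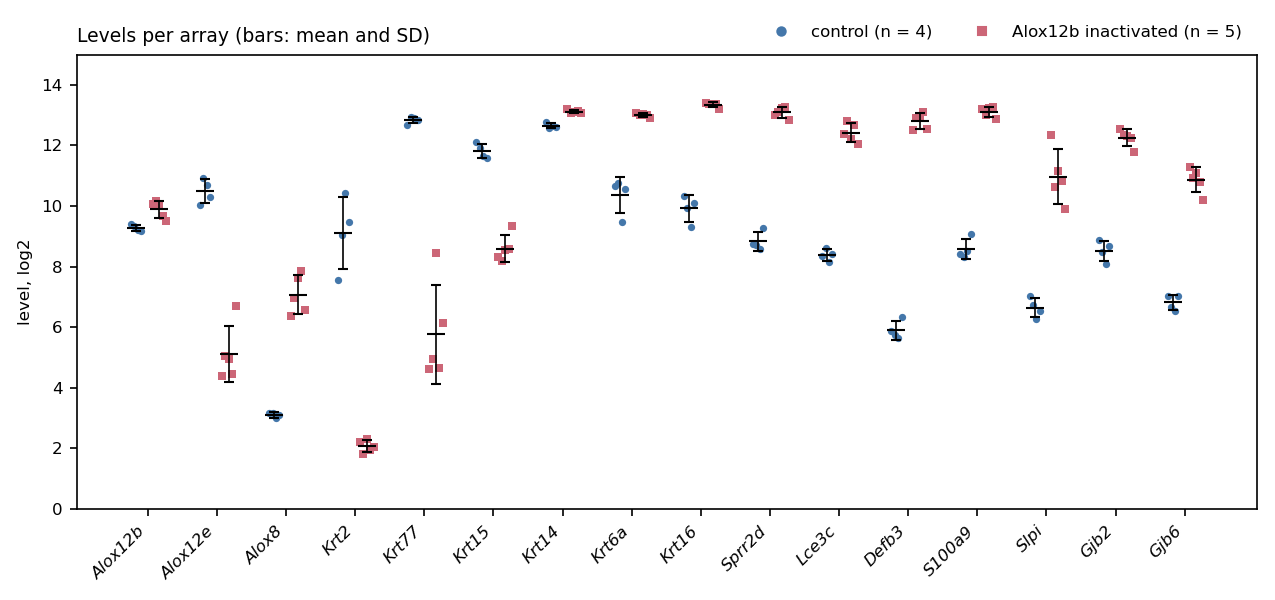
Levels of 16 genes on each array, on the log2 scale of the deposited values. Circles are the 4 control arrays and squares the 5 inactivated arrays, with black bars for the mean and SD. Krt77 fell from 12.85 to 5.76 and Defb3 rose from 5.89 to 12.80.

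Antimicrobial proteins and alarmins rose in 15 of 24 measured members, with 4 lower and 5 not passing (17 and 4 adjusted over the list alone; camera adjusted p = 1.72e-05, adjusted p = 0.380 with an estimated correlation). The beta-defensin Defb3 showed the largest rise of any gene that passed without overlap, 6.91 ± 0.16 or 121-fold. Defb4 rose by 4.17 ± 0.27, and the calprotectin subunits S100a9 and S100a8 rose by 4.54 ± 0.15 and 3.40 ± 0.15. Wfdc21 fell by 3.37 ± 0.26 and the lysozyme Lyz1 by 0.79 ± 0.15. Protease inhibitors moved with them, with 12 of 19 higher, 3 lower and 4 not passing (12 and 4 adjusted over the list alone; camera adjusted p = 0.000862, adjusted p = 0.294 with an estimated correlation). Spink12 rose by 5.43 ± 0.31, the stefin Stfa2l1 by 4.29 ± 0.28, and Serpinb6c and Serpinb2 by 2.01 ± 0.11 and 1.27 ± 0.11. Serpinb7 fell by 1.48 ± 0.37 and Spint2 by 0.26 ± 0.06. Slpi, an elastase inhibitor, rose by 4.33 ± 0.39.

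Kallikreins and other proteases of desquamation rose in 19 of 24 members, with 1 lower and 4 not passing (20 and 2 adjusted over the list alone; camera adjusted p = 7.31e-09, adjusted p = 0.294 with an estimated correlation). Klk12 rose by 3.55 ± 0.25, Klk13 by 3.10 ± 0.16, Klk6 by 2.26 ± 0.11 and Klk9 by 1.68 ± 0.14, and the calpain Capn1 fell by 0.25 ± 0.08. The serine protease Tmprss11a rose by 5.01 ± 0.46. Some kallikreins of the glandular subfamily, which was not tested as a group, were lower. Klk1b24 fell by 4.51 ± 0.54 and, named after their values were seen, Klk1b27 fell by 3.004 ± 0.338, Klk1b21 by 2.58 ± 0.41 and Klk1b1 by 1.87 ± 0.40, while Klk1 and 5 other Klk1b genes did not pass.

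Cell junction genes went both ways, with 8 of 28 higher, 11 lower and 9 not passing (9 and 11 adjusted over the list alone; camera adjusted p = 0.810). The gap junction proteins Gjb6 and Gjb2 rose by 4.05 ± 0.20 (16.6-fold) and 3.73 ± 0.17 (13.2-fold), while Gjb5 fell by 2.81 ± 0.25 and the tricellular junction protein Marveld2 by 1.58 ± 0.12. Extracellular matrix, integrin and basement membrane genes had 5 of 27 higher, 7 lower and 15 not passing (5 and 7 adjusted over the list alone; camera adjusted p = 0.927). The gelatinase Mmp9 fell by 1.90 ± 0.10, the anchoring fibril collagen Col7a1 by 1.27 ± 0.09, Fn1 by 1.89 ± 0.25 and Col17a1 by 0.91 ± 0.14, whereas the integrins Itga3 and Itgb6 rose by 0.49 ± 0.09 and 0.58 ± 0.12.

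Interleukin 1 family members rose in 8 of 15 genes, with 1 lower and 6 not passing (9 and 2 adjusted over the list alone; camera adjusted p = 0.0106, adjusted p = 0.485 with an estimated correlation). Il1f6 rose by 2.40 ± 0.15, Il1a by 1.77 ± 0.16, Il1f8 by 1.43 ± 0.15 and Il1f5 by 0.76 ± 0.09. The decoy receptor Il1r2 fell by 1.22 ± 0.17. In the interleukin 17 and 23 axis, 8 of 18 rose, 3 fell and 7 did not pass (8 and 3 adjusted over the list alone; camera adjusted p = 0.0892, and 0.0457 without inactivated replicate 2). Zc3h12a and Nfkbiz, which regulate the response to these cytokines, rose by 1.31 ± 0.12 and 0.97 ± 0.15, while the receptor chains Il20ra and Il20rb fell by 2.35 ± 0.37 and 1.89 ± 0.28. Of 24 genes of type 2 immunity, 9 rose, 4 fell and 11 did not pass (11 and 5 adjusted over the list alone; camera adjusted p = 0.270). Arginase (Arg1) rose by 2.54 ± 0.21, and Gata3, Postn and Ccl8 fell by 1.50 ± 0.16, 1.94 ± 0.25 and 1.27 ± 0.18. Most chemokines did not pass, with 3 of 26 higher, 1 lower and 22 not passing (2 and 1 adjusted over the list alone; camera adjusted p = 0.413). Cxcl1 and Cxcl2, which attract neutrophils, rose by 0.80 ± 0.19 and 1.50 ± 0.51. The Cxcl2 difference was 0.997 without inactivated replicate 1. The Cxcl1 value is from the probe set with the highest mean, and the other Cxcl1 probe sets rose by 3.23 ± 0.32 and 2.56 ± 0.35. Ccl6 rose by 1.04 ± 0.25, and Ccl27a fell by 1.66 ± 0.10 on the single probe set assigned to that gene alone.

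Interferon-induced genes fell in 16 of 29 members and rose in none, with 13 not passing (18 lower adjusted over the list alone). Camera called the list lower (adjusted p = 4.38e-05; adjusted p = 0.539 with an estimated correlation). The list's median against the control mean was -0.15 on inactivated replicate 5, within the control range of -0.24 to 0.30, and -0.76 to -0.42 on the other inactivated arrays. Ifih1, a sensor of viral RNA, fell by 0.97 ± 0.13, Xaf1 by 1.08 ± 0.18, Irf9 by 0.85 ± 0.14 and Ifi27 by 0.77 ± 0.10. Of the macrophage markers, 1 of 18 was higher, 7 were lower and 10 did not pass (1 and 9 adjusted over the list alone; camera adjusted p = 0.00902, adjusted p = 0.656 with an estimated correlation). Their median against the control mean was 0.01 on inactivated replicate 1 and -0.75 to -0.27 on the other inactivated arrays, against -0.13 to 0.17 on the controls. Fibroblast markers had medians of -1.52 to -0.66 on the inactivated arrays.

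Ligands and feedback genes of the EGF receptor, which controls keratinocyte growth, had 8 of 19 higher, 3 lower and 8 not passing (8 and 3 adjusted over the list alone; camera adjusted p = 0.115). Epiregulin (Ereg) rose by 1.96 ± 0.16, Etv4 by 1.46 ± 0.14, Nrg1 by 1.37 ± 0.13 and Dusp5 by 1.11 ± 0.14, and Spry2 and the receptor Erbb2 fell by 0.86 ± 0.11 and 0.70 ± 0.09. Immediate early genes rose in 9 of 22 members, with 1 lower and 12 not passing (12 and 1 adjusted over the list alone; camera adjusted p = 0.00681, adjusted p = 0.613 with an estimated correlation). Ier3 rose by 1.93 ± 0.15, Zfp36 by 1.18 ± 0.18 and Junb by 0.82 ± 0.12, and Egr2 fell by 0.71 ± 0.09. Of 38 proliferation genes, 9 rose, none fell and 29 did not pass (9 adjusted over the list alone; camera adjusted p = 0.0535). The ribonucleotide reductase subunits Rrm2 and Rrm1 rose by 1.16 ± 0.11 and 0.49 ± 0.11, and Ccne1 and Cdc20 by 0.68 ± 0.09 and 0.64 ± 0.12. This list passed without inactivated replicate 1 (adjusted p = 0.00277), without inactivated replicate 3 (adjusted p = 0.0312) or without control replicate 1 (adjusted p = 0.00774).

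Genes of glycolysis and hypoxia rose in 13 of 20 members, with 1 lower and 6 not passing (13 and 1 adjusted over the list alone; camera adjusted p = 1.01e-05, adjusted p = 0.485 with an estimated correlation). Pgam1 rose by 0.92 ± 0.11, Tpi1 by 0.86 ± 0.10, Pkm by 0.84 ± 0.09 and Ldha by 0.79 ± 0.09. The hexokinase Hk1 fell by 0.27 ± 0.08, and its other probe set read -0.95. Cholesterol synthesis genes rose in 12 of 20 members, with 1 lower and 7 not passing (14 and 1 adjusted over the list alone; camera adjusted p = 4.01e-05, adjusted p = 0.487 with an estimated correlation). Lss rose by 1.17 ± 0.12, Idi1 by 0.91 ± 0.08, Msmo1 by 0.59 ± 0.06 and Pmvk by 0.57 ± 0.08, whereas Dhcr7, which makes cholesterol in the last step, fell by 0.30 ± 0.08. Fatty acid synthesis had 4 of 25 higher, 7 lower and 14 not passing (4 and 7 adjusted over the list alone; camera adjusted p = 0.873). Elovl7 rose by 0.58 ± 0.08, and Elovl5, Srebf1 and Gpam fell by 1.28 ± 0.21, 0.58 ± 0.13 and 0.51 ± 0.11.

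Among PPAR receptors and targets, 3 of 25 rose, 3 fell and 19 did not pass (2 and 3 adjusted over the list alone; camera adjusted p = 0.810). The receptor Ppard rose by 1.42 ± 0.09 and Ppara fell by 2.19 ± 0.23. The other Ppara probe sets read -1.17 and -0.46, and the other Ppard probe set read 0.79. Fabp5, a fatty acid carrier, rose by 0.47 ± 0.06 and Vnn1 fell by 1.85 ± 0.35. That Fabp5 probe set read 13.36 in the inactivated group, near the top of the array range. The other Fabp5 probe set rose by 1.13 ± 0.10. NRF2 targets, which detoxify oxidants, had 10 of 24 higher, 5 lower and 9 not passing (11 and 5 adjusted over the list alone; camera adjusted p = 0.324). Gsta4, a glutathione transferase for lipid aldehydes, rose by 4.32 ± 0.34, the cystine transporter Slc7a11 by 3.52 ± 0.21 (11.5-fold) and Txn1 by 0.65 ± 0.08, and Gstm1 and Abcc4 fell by 1.43 ± 0.08 and 0.72 ± 0.10. The unfolded protein response had 6 of 22 higher, 4 lower and 12 not passing (7 and 4 adjusted over the list alone; camera adjusted p = 0.499), with Ero1a up by 0.94 ± 0.08, Chac1 up by 0.79 ± 0.17 and Ddit3 lower by -0.52 ± 0.12. Retinoid metabolism had 6 of 23 higher, 7 lower and 10 not passing (6 and 7 adjusted over the list alone; camera adjusted p = 0.873). The retinol carrier Rbp2 rose by 1.87 ± 0.16, Crabp2 by 1.01 ± 0.12 and Rdh12 by 0.64 ± 0.08, and Dhrs3 fell by 1.15 ± 0.12.

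Circadian clock genes had 3 of 17 higher, 7 lower and 7 not passing (3 and 8 adjusted over the list alone; camera adjusted p = 0.243). The clock output factors Hlf and Dbp fell by 2.79 ± 0.15 and 2.52 ± 0.38 and Nr1d2 by 1.22 ± 0.13, and Nfil3, a repressor of the same output sites, rose by 0.82 ± 0.21 with Clock at 0.56 ± 0.08. The other Clock probe sets did not pass, at -0.30, 0.00428 and 0.16. The hour of sampling is not given in the sources used here. For several lists that camera did not call, its direction differed in sign from the median or mean of the members. The medians and means were -0.01 and -0.01 for the lipoxygenases, 0.13 and -0.11 for fatty acid synthesis, -0.04 and -0.02 for PPAR targets and -0.05 and -0.15 for sebaceous markers, each tested as higher. They were 0.02 and 0.03 for cell junctions, -0.03 and 0.00402 for retinoid metabolism and 0.12 and -0.13 for matrix genes, each tested as lower.

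**Figure D2:**
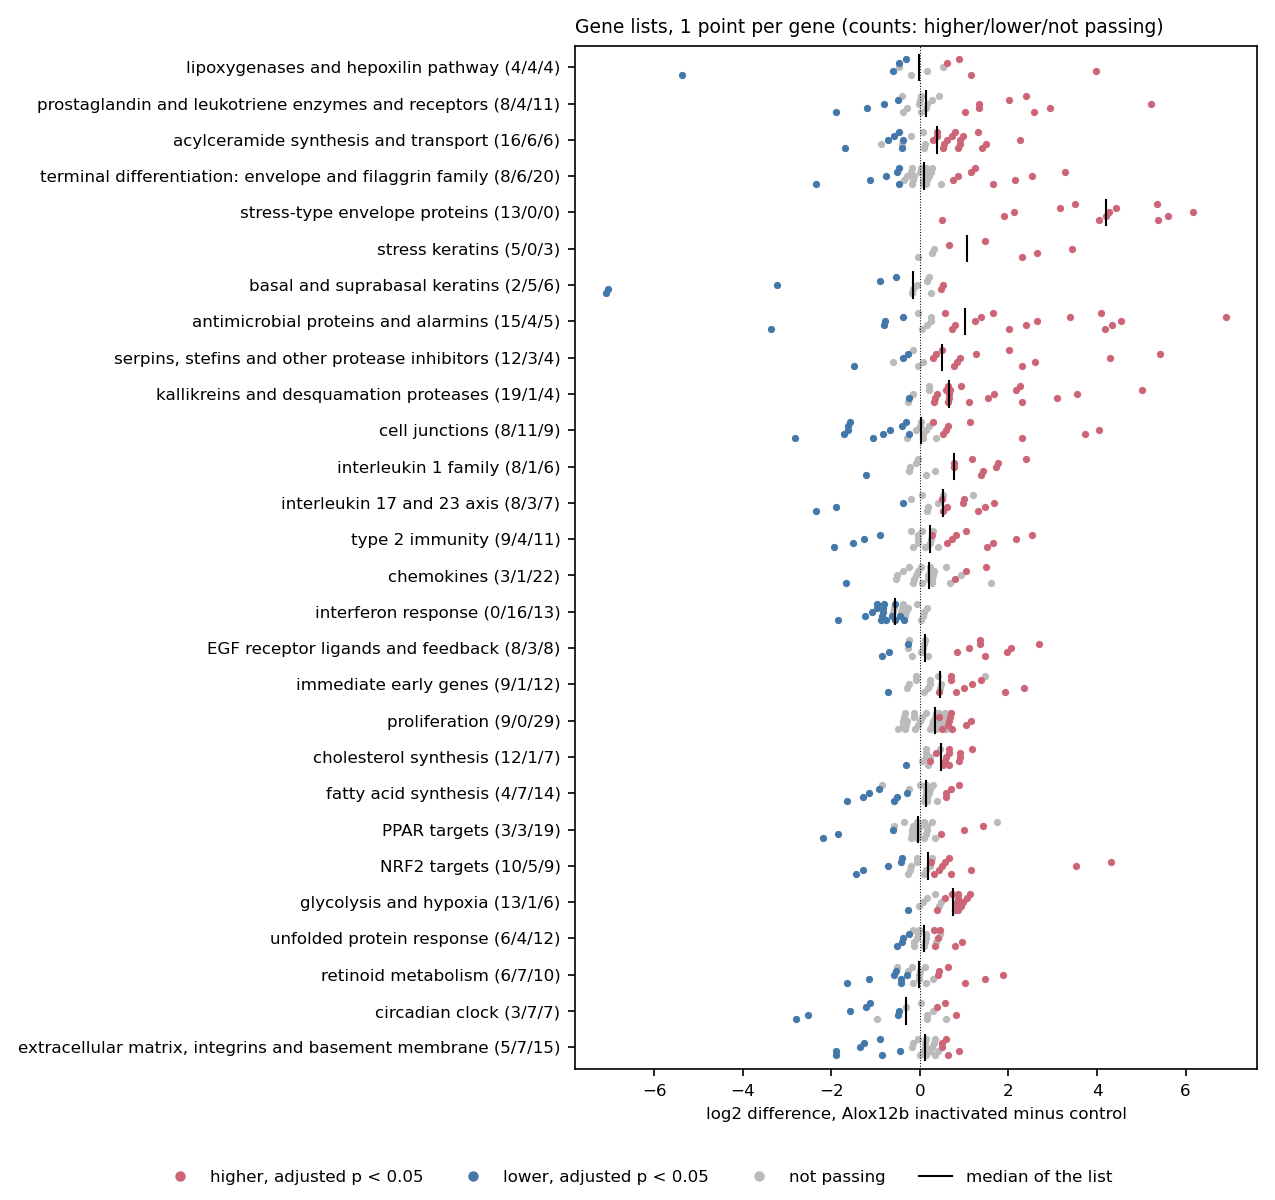
Log2 difference (inactivated minus control) of each measured member of 28 gene lists, 1 point per gene. Red and blue points rose or fell past the threshold, grey points did not pass, black lines are list medians, and the numbers beside each name count higher, lower and not passing members. All 13 stress-type envelope genes lie above 0, with a median of 4.20.

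The remaining lists hold markers of other cell types of skin, which an epidermal preparation can carry. Fibroblast markers fell in 15 of 17 members and rose in none, with 2 not passing and a median of -1.12 (16 lower adjusted over the list alone; camera adjusted p = 6.88e-07, adjusted p = 0.487 with an estimated correlation). Thbs2 fell by 1.69 ± 0.20, Loxl1 by 1.93 ± 0.28, dermatopontin (Dpt) by 1.08 ± 0.17 and lumican (Lum) by 1.01 ± 0.16. Smooth muscle markers fell in 9 of 10 members (9 adjusted over the list alone; camera adjusted p = 0.000373, adjusted p = 0.487 with an estimated correlation), with Tagln lower by -0.92 ± 0.16 and Synpo2 by -0.80 ± 0.12. Of the endothelial markers, 2 of 15 rose, 1 fell and 12 did not pass (2 and 1 adjusted over the list alone; camera adjusted p = 0.873). Lyve1, a lymphatic marker, rose by 1.99 ± 0.24, Emcn rose by 0.61 ± 0.17 and Vwf fell by 0.66 ± 0.18. Among nerve sheath markers, Pmp22 and Cnp fell by 1.16 ± 0.17 and 0.82 ± 0.16 and Sox10 rose by 0.30 ± 0.09, with 1 of 8 higher, 3 lower and 4 not passing (1 and 3 adjusted over the list alone; camera adjusted p = 0.292).

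T cell markers divided, with 4 of 17 higher, 5 lower and 8 not passing (4 and 5 adjusted over the list alone; camera adjusted p = 0.243). The receptor chains Cd3g, Cd247 and Cd3d fell by 2.498 ± 0.175, 1.13 ± 0.11 and 0.83 ± 0.12 and Thy1 by 1.57 ± 0.16, while the activation markers Icos and Ctla4 rose by 0.66 ± 0.12 and 0.60 ± 0.17. Skint10, a member of the Skint gene family, fell by 5.90 ± 0.58. Langerhans and dendritic cell markers had 2 of 17 higher, 6 lower and 9 not passing (2 and 6 adjusted over the list alone; camera adjusted p = 0.636), with Cd207, the langerin of Langerhans cells, lower by -0.98 ± 0.24 and the migration receptor Ccr7 up by 1.38 ± 0.23. Among the macrophage markers, Adgre1 fell by 0.94 ± 0.16, Csf1r by 0.82 ± 0.14 and Lyz2 by 0.81 ± 0.17, and Fcgr1 rose by 0.35 ± 0.09 on 1 probe set and read -0.32 ± 0.22 on another, which did not pass. Neutrophil markers had 7 of 16 higher, 2 lower and 7 not passing (7 and 2 adjusted over the list alone; camera adjusted p = 0.108), with Pglyrp1 up by 2.39 ± 0.26, Mmp8 by 1.46 ± 0.30 and Mpo lower by -1.41 ± 0.33. Mast cell markers had 2 of 10 higher and 8 not passing (2 adjusted over the list alone; camera adjusted p = 0.472), with Hdc up by 1.42 ± 0.26 and Kit by 0.38 ± 0.11.

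Melanocyte markers rose in 7 of 11 members, with 4 not passing (7 adjusted over the list alone; camera adjusted p = 0.00401, adjusted p = 0.487 with an estimated correlation). Dct, Mlana and Tyrp1, genes of pigment synthesis and melanosomes, rose by 2.78 ± 0.39, 2.21 ± 0.38 and 2.09 ± 0.36, and the other Tyrp1 probe sets rose by 3.97 and 2.78. Hair follicle markers had 10 of 34 higher, 3 lower and 21 not passing (10 and 3 adjusted over the list alone; camera adjusted p = 0.0276, adjusted p = 0.656 with an estimated correlation). The call ended with sex in the model (adjusted p = 0.0644) and without inactivated replicate 3 (adjusted p = 0.0562) or replicate 4 (adjusted p = 0.0536). Krt84 rose by 1.72 ± 0.25 and Gsdma by 0.77 ± 0.08. Lgr6 and Cd34, also on this list, fell by 2.08 ± 0.23 and 1.30 ± 0.22. The other Lgr6 probe set read -0.29. Skeletal muscle markers had 2 of 17 higher and 15 not passing (none adjusted over the list alone; camera adjusted p = 0.0624), with Tnni2 at 1.84 ± 0.54 and Mb at 0.56 ± 0.18. Their median lay 2.49 above the control mean on inactivated replicate 4 and 0.53 or less above it on the other inactivated arrays. The list passed without inactivated replicate 1 (adjusted p = 0.0280), replicate 2 (adjusted p = 0.0457) or replicate 5 (adjusted p = 0.0221).

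Adipocyte markers had 2 of 11 higher and 9 not passing (2 adjusted over the list alone; camera adjusted p = 0.477), with Lipe and Cidea up by 0.51 ± 0.12 and 0.51 ± 0.16. Sebaceous gland markers had 2 of 12 higher, 1 lower and 9 not passing (2 and 1 adjusted over the list alone; camera adjusted p = 0.927), and Scd3 fell by 1.66 ± 0.51. Blood markers had 1 of 7 higher, 1 lower and 5 not passing (1 and 1 adjusted over the list alone; camera adjusted p = 0.810), with Hba-a1 up by 0.33 ± 0.10 and Bpgm lower by -0.20 ± 0.06. None of the 4 sex-linked genes passed (none adjusted over the list alone; camera adjusted p = 0.705).

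**Figure D3:**
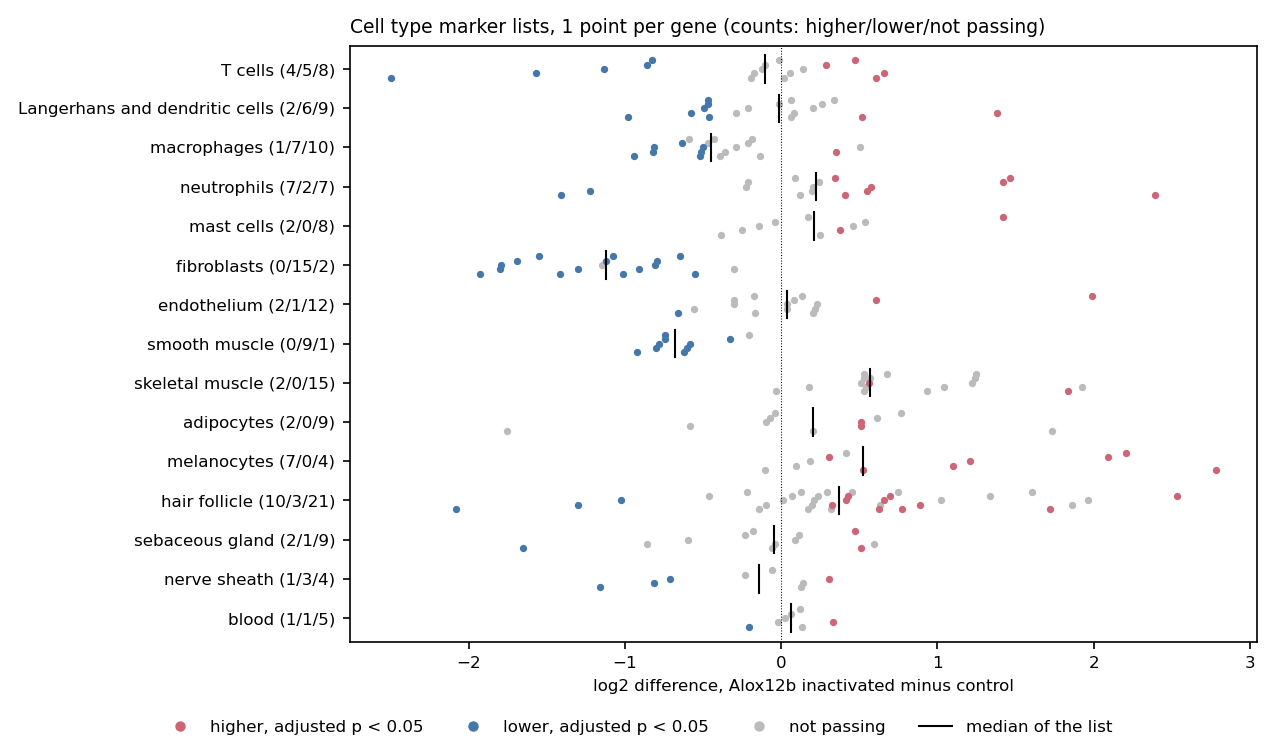
Log2 difference (inactivated minus control) of each measured marker in 15 cell type lists, 1 point per gene. Colours, black median lines and counts are as for the other gene lists. Fibroblast markers have a median of -1.12 and endothelial markers a median of 0.04.

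Several of the largest changes were in genes outside the lists. Urate oxidase (Uox) rose by 5.11 ± 0.30 (34.5-fold). Dapl1 fell by 5.08 ± 0.45, the calcium-binding protein Tesc by 4.91 ± 0.20, the axon guidance ligand Sema3d by 4.91 ± 0.14 and the decarboxylase Gadl1 by 4.75 ± 0.21. Fcgbp fell by 4.26 ± 0.16, the tetraspanin Tspan8 by 3.80 ± 0.24 and Bbox1, the last enzyme of carnitine synthesis, by 3.77 ± 0.40.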

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

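Chosen only after their results were seen were the tests of sex in replicate 5, of the unequal sex numbers, of group effects that differ by sex, and of endothelial against fibroblast and smooth muscle markers.

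Among 209 named genes, the highest or lowest array stood apart from the rest of its group (Dixon's ratio above its 95% critical value) in 39 of 418 groups, or 9.33%, where chance gives about 1 in 20. Inactivated replicate 5 accounted for 14 of these and control replicate 1 for 13. Inactivated replicate 5 was the lowest of its group for genes that rose, with log2 levels of 10.21 for Sprr2i, 9.59 for Sprr2f, 7.33 for Pla2g4d, 7.92 for Uox, 12.13 for Cnfn, 13.21 for Krt16, 11.40 for Klk13 and 6.79 for Slc7a11. It was the highest of its group for genes that fell, with 6.70 for Alox12e, 4.52 for Cysltr1, 7.43 for Ifih1, 9.01 for Egr2, 6.92 for Gstm1 and 6.15 for Cd3g. All 14 lay on the side of the controls.

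Control replicate 1, the only female control by its Xist level of 11.38 and its Uty level of 2.83, was the lowest control for Ephx3 (9.01), Thy1 (9.07), Loxl1 (6.999), Lum (10.80), Dpt (9.24), Lipe (6.02) and Pmp22 (9.49). It was the highest for Pla2g4d (2.94), Il1f6 (9.85), Rrm1 (8.504) and Lyve1 (5.88). Other arrays stood apart in single genes. Control replicate 2 was highest for Serpinb6c (6.90) and Ltc4s (5.62), control replicate 3 lowest for Lce3a (4.32) and Krt6a (9.48), and control replicate 4 highest for Ccl8 (11.997). Inactivated replicate 1 was lowest for Serpinb7 (7.76) and highest for Ccr7 (6.02). Inactivated replicate 2 was lowest for Icos (5.83), Myh11 (5.09) and Scd3 (3.82), and inactivated replicate 3 was lowest for Spint2 (10.52) and highest for Ldha (11.69).

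The interaction term of limma, between group and the sex read from the data, picked out probe sets of Capn9 and Phgdh. They were not chosen by the rule for named genes. The effect in males minus that in females was 3.78 for Capn9 and 5.79 for a probe set of Phgdh. Both rest on a single female control, control replicate 1, which read 6.99 for Capn9 and 8.40 for the Phgdh probe set, apart from the other controls. A difference by sex therefore cannot be told from a difference of that 1 array.

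The intermediate place of inactivated replicate 5 was weighed first. Sex alone was argued against, because another female inactivated array had the highest score of all on the first principal component, 55.8. The third female inactivated array scored 44.9, below both male inactivated arrays (48.5 and 53.6). A part played by sex therefore stays open. Admixture of control-like tissue predicts a single share for genes of both directions. The median share implied on the linear scale was 0.379 (quartiles 0.225 to 0.569) by 495 genes that rose and 0.151 (quartiles 0.0470 to 0.276) by 683 genes that fell, a difference of 0.228. The quartiles overlap, so admixture, incomplete inactivation and a slower response in this mouse cannot be told apart, and the last 2 were not tested.

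The fall of fibroblast and smooth muscle markers was weighed next. Less dermis on the sheets of the inactivated group would lower the markers of all dermal cells alike, but endothelial markers with control levels of 5 to 8.5 had a median difference of 0.036 (quartiles -0.30 to 0.21, 12 genes), against -0.78 (quartiles -1.14 to -0.65, 13 genes) for fibroblast and smooth muscle markers of that range, and between 5 and 7 the medians were 0.037 (11 genes) and -0.76 (6 genes). The most abundant endothelial markers, Plvap and Vwf, went from 7.98 and 6.84 to 7.82 and 6.18, and the fibroblast markers Col1a2 and Col3a1 from 12.88 and 12.66 to 11.58 and 11.75, with no member of these lists on another list. Array scaling was also argued against, since after quantile normalisation the median of the fibroblast markers was -1.08. The falls of Vwf, of 7 of 18 macrophage markers and of 3 of 8 nerve sheath markers, neither list called with an estimated correlation, go with a loss of dermis, so a change within fibroblasts, or a rise of endothelial cells that offsets such a loss, stays open.

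The number of changed genes was weighed last. Of 100 splits drawn from the 126 of the 9 arrays, only the real one, 1 of 100, gave as many changed probe sets (12900, highest other 8621), genes (6250, highest other 4345) or genes changed at least 2-fold (1050, highest other 819). This argues against chance for these counts, though 1 of 100 is the smallest share these splits can give. The highest other split is nearly the mirror of the real one, with inactivated replicate 5 alone set beside the controls, and the next gave 1669 probe sets. For gene lists, 27 of 100 splits gave as many camera calls as the real 16. The other splits gave a median of 12 and at most 21, so chance cannot be excluded for the number of lists. With sex in the model, 87.6% of the called probe sets were still called, which argues against the unequal sex numbers as the main cause. That the changed genes respond to the loss of Alox12b may be put as a hypothesis only, since active Cre, absent from all controls, went with it and was not tested.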

How the results depend on the processing

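For the gene lists, sex as a covariate and quantile normalisation were added after the data were seen, as was leaving out arrays for the array interquartile range; the other settings were planned. Counts of changed probe sets and genes stayed within 1.5 times the values reported under all settings but the stricter threshold of 0.01, which by construction lowered them to 2932 higher and 4377 lower probe sets and 1526 higher and 2179 lower genes. Across single arrays left out, probe sets ranged from 4161 to 5931 higher and 5753 to 7381 lower, genes from 2091 to 2847 higher and 2753 to 3585 lower, genes changed 2-fold from 412 to 495 higher and 560 to 683 lower, the difference of Alox12b from 0.54 to 0.71, the lists called by camera from 15 to 18 and the difference in array interquartile range from -0.18 to -0.14. The share of higher genes was 45.1% as deposited, 50.3% after quantile normalisation and 54.0% after subtracting array medians. None of the 209 named genes changed sign under any setting in which it was computed. Of them, 28 lost their call at 0.01, 14 without control replicate 3, 13 without control replicate 4 and 13 with no moderation. Calls were lost by 11 without control replicate 2, 8 with the replicate block and at most 7 under each other setting computed. Named genes were not computed with removal of probe sets that can match several transcripts. With that removal, 6 of 6159 gene calls over all genes turned. Of 6250 gene calls, 6 turned with the mean of all probe sets and 1 after quantile normalisation. The deviations of same-numbered arrays from their group means had correlations of -0.27 to 0.08. These correlations cannot show whether the numbers pair the mice, and the sources used here do not say. With the replicate block, in which replicate 5 has no partner, 2256 genes were higher and 3089 lower, and 80.4% of the gene calls were kept. The gene lists depended most on the test. Of 44 lists, 16 passed camera, 0 passed with an estimated correlation and 26 passed fry, which does not compare a list with other genes; the cause was not tested. The lists whose direction turned passed neither as reported nor in the turned setting, with adjusted p as follows. Cell junctions (0.451) and retinoid metabolism (0.331) turned with fry, fatty acid synthesis with the mean of all probe sets (0.961) and quantile normalisation (0.985), matrix genes with the replicate block (0.766) and sex (0.972), and sebaceous markers with the replicate block (0.881) and quantile normalisation (0.896). With single arrays left out, adjusted p ranged from 0.648 to 0.997 for fatty acid synthesis, 0.571 to 0.997 for PPAR targets, 0.606 to 0.989 for matrix genes, 0.484 to 0.985 for endothelial markers and 0.484 to 0.989 for sebaceous markers. All but matrix genes turned without inactivated replicate 4 or control replicate 1, endothelial and sebaceous markers also without inactivated replicate 1, matrix genes without inactivated replicate 2 or 5, and sebaceous markers also without replicate 5. Camera also called the EGF receptor list (0.0368) and proliferation (0.0482) with the mean of all probe sets, proliferation after quantile normalisation (0.0147) and skeletal muscle markers with the replicate block (0.00841); fry did not call macrophage (0.0712) or hair follicle markers (0.0545). The causes were not tested. The check of RNA quality from control probe sets was not run. Transcripts near the floor or the top of the array range limit what a difference there can show.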

Other observations

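The enrichment of gene families by name, and the probe sets with steps within a group, were chosen after the data were seen. Of 425 families of at least 6 measured genes that share the start of their symbol, 8 held more genes changed at least 2-fold in 1 direction than a hypergeometric test gives, adjusted over 850 tests. The test treats genes as independent, while members of a family can change together or share probes. Its adjusted p-values do not measure the spread between mice and may be too small. Members higher and lower by at least 2-fold numbered 8 and 0 of 9 Sprr, 5 and 1 of 18 Serpinb, 5 and 4 of 20 Klk, 3 and 0 of 6 Tgm and 4 and 2 of 15 Lce genes, of which Lce had a median of -0.19. The others were beta-tubulins, calcium-activated chloride channel regulators and collagens, whose members below were named after their values were seen. Of 9 beta-tubulin genes, 4 rose at least 2-fold (adjusted p = 0.0111). Tubb3 rose by 2.61 ± 0.14, Tubb6 by 2.44 ± 0.17, Tubb2b by 1.52 ± 0.24 and Tubb2a by 1.12 ± 0.14. Of 8 Clca genes, 4 fell at least 2-fold (adjusted p = 0.0132). Clca3a2 fell by 3.69 ± 0.22, Clca3a1 by 3.13 ± 0.19 and Clca2 by 1.12 ± 0.11, and related copies of this family can share probes. Of 42 collagen genes, 9 fell at least 2-fold and 1 rose (adjusted p = 0.00346 for the fall), among them the basement membrane collagen Col4a5, which fell by 2.31 ± 0.17, and Col14a1, which fell by 2.19 ± 0.27. Of these 9, Col1a1, Col1a2 and Col5a1 are on the fibroblast list, which fell in 15 of 17 members with a median of -1.12. For each of the 8 families the number of members changed 2-fold in either direction was the same after quantile normalisation, subtraction of array medians and cyclic loess, and 0 of these members turned.

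Some probe sets moved in steps within a group. A Phgdh probe set read 8.40 to 9.27 on all inactivated arrays and control replicate 1 and 2.40 to 2.79 on the other 3 controls, while the Phgdh probe set with the highest mean stayed between 8.78 and 9.28 on all arrays. Capn9 read 6.99 on control replicate 1 and at most 3.20 on the other arrays. Slc15a2 read 4.03 on control replicate 1 and 8.12 to 9.76 on the others. Mndal read 5.31 on inactivated replicate 2, 6.19 on control replicate 4 and at most 1.55 elsewhere. Inactivated replicate 4 carried high levels of muscle and fat transcripts, with Myh4 at 7.88, Car3 at 10.76 and Adipoq at 8.30, and the median of the adipocyte markers there lay 2.38 above the control mean.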
